A study of Mus musculus with 3 samples.

How the data were processed

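Gene expression was measured in 3 bone marrow libraries of the vehicle group, numbered as in the labels, and herb-treated samples were not analysed here. Per the labels' protocols, RNA was extracted with Trizol and 500 ng of total RNA entered a Lexogen QuantSeq library kit, which primes at the poly(A) tail and gives about 1 fragment per transcript, so no length correction was applied. Bowtie2, bedtools and the mm10 build are named in the submitters' processing notes. Their versions, the gene annotation, the strand setting and the normalization rule are not given in the sources used here, so overlapping and antisense genes were not separated by strand.

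The authors deposited 1 file per library with a gene symbol and a log2 value, read from the values themselves as log2(x + 1) with x in reads per 1000000 of a scaled library size. Within a library, 2 raised to the deposited value, minus 1, was a whole multiple of what 1 read was worth, for 100% of values within a tolerance of 1e-06, so whole reads per gene were recovered. The authors' denominators were 1.12, 1.03 and 1.01 times the recovered reads in replicates 1, 2 and 3. The files held 23282 entries with 23238 distinct symbols, of which 35 symbols stood in more than 1 entry, and 16040 entries had reads. Of the symbols, 22197 matched the GENCODE annotation of GRCm38, the assembly called mm10, and the gene positions printed are from that annotation. Whether neighbouring entries overlap was read from the NCBI RefSeq annotation of the same assembly. Genes of the mitochondrial genome, and the immunoglobulin and T cell receptor constant genes, Ahsp and Epb42 of the lists, were not analysed here, and 457 of the 469 list members were measured. Rn45s held 18.8%, 20.3% and 18.6% of reads and globin entries 10.1%, 15.1% and 15.0%, and both stayed in the library totals. Some neighbouring entries held reads within 2% of each other in every library. The second entries of such pairs held 2.86%, 4.14% and 4.03% of reads and stayed in the library totals as well.

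The design had assumed read counts, and the files held log2 values. The exact tests therefore ran on the recovered reads, and the planned dispersion estimate was replaced by its stated substitute, the median SD of the deposited log2 values over 3 libraries. That substitute had been set for normalized values only, and it includes counting noise. DESeq2 and edgeR were not used, a choice made because the deposited unit is log2, although the recovered reads would have allowed a count-based estimate. TMM factors (30% of ratios and 5% of intensities trimmed) and median-of-ratios factors were computed in Python instead. CPM values are recovered reads per 1000000 recovered reads of the library.

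Each gene with at least 30 reads over the 3 libraries was tested with an exact two-sided binomial test of each library against the other 2, the smallest of the 3 p-values was multiplied by 3, and Benjamini-Hochberg adjustment followed at 0.05. These choices, the 31 gene lists, the tests and the rule for named genes were fixed before the data were examined. List levels are summed member reads as a percent of all reads, with mean and SD over 3 libraries and exact 95% Clopper-Pearson intervals per library, whose width to either side had a median of 1.76% of the value and at most 17.7%. List sums were tested in the same way with and without the most abundant member, and the median member CV was set against 10000 random lists matched on size and expression. These percentiles were computed on library totals only. The ratios of the neutrophil lists were tested by an exact two-sided sign-flip permutation. Some lists share members, such as Myb and Il1b, and bulk list levels are no share of cells.

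The named genes were the 20 most abundant genes, the 3 most abundant members of each list, the 15 genes with the largest CV among those past the test with a mean of at least 20 CPM, and the members of the stem and progenitor list and of the Y chromosome and Xist list. The text gives a part of these. Klf1, Ccr3, Siglecf, Il5ra, Prg3, Cpa3, Mcpt8, Prss34, Ms4a2, Fcer1a, Fabp4, Cfd, Lepr, Atf3, Fosb, Rag1 and Dntt fall outside that rule and were chosen after the data were seen, as were the 6 lists followed through the alternatives one by one.

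The binomial test was tested on simulated counts of the 3 libraries, with 200 genes of at least 300 reads changed in 1 library. It called 40% of 50 genes changed 1.2-fold (20 genes), 96% of 50 changed 1.5-fold (48 genes) and 100% of 50 changed by a factor of 2 or 3. It also called 63 of 11608 unchanged genes (0.543%), more than the true calls at any 1 fold change. With no gene changed it called 0 of 11820. The simulated counts held counting noise only, which the test itself assumes, so these results do not cover libraries with added spread. Alternatives covered the scaling, the read minimum, a chi-square test, the pseudocount, leaving out the 20 most abundant genes and leaving out each library. Leaving out the library furthest from the other 2 narrows a spread by construction, so it shows where the spread lay and not its source. For lists and genes it was done on library totals only, so where the spread lay may differ with another scaling. An SD or CV of 2 libraries also tends to be lower than that of 3 at equal spread. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.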

Results

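Bone marrow cells of male wild type C57BL/6 mice, a common inbred laboratory strain, were profiled by RNA sequencing from the polyadenylated end of transcripts. The series compares sterile water, the vehicle, with Asari Radix et Rhizoma, the dried root and rhizome of a wild ginger used in herbal medicine, and its title names haematopoietic stem cells as the subject. Only the vehicle arm is described, with 3 libraries, and herb-treated samples were not analysed here, so no value below compares treatments. The mice were 6 weeks old, received 28 days of oral gavage and were harvested on day 29, and red blood cells were lysed before RNA extraction. The libraries held 9168435, 8104828 and 9137125 gene-assigned reads in vehicle replicates 1, 2 and 3, with reads in 14599, 14384 and 14507 genes. At these depths a count of 0 allowed a level of up to 0.327, 0.370 and 0.328 reads per 1000000 gene-assigned reads (CPM, the unit of gene levels throughout). Intervals and floors cover counting error only, since the sources used here name no molecular identifiers. The floors hold only for genes whose reads could be counted, and a 0 alone does not show that they could, since the gene annotation is not given. The labels do not say that the libraries came from separate mice, so the spread between these samples may be technical. The p-values test that spread against counting noise only. They also depend on read number, so a small p-value does not give the size of a spread. Directions given for whole lists held with trimmed-mean (TMM) scaling and with the authors' scaling unless a sentence says otherwise.

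Ribosomal RNA, globins and neutrophil calcium-binding proteins took the largest shares of the reads. The precursor ribosomal RNA gene Rn45s alone held 19.2% ± 0.907 of reads (SD, n = 3). The α-globin gene Hba-a1 (GRCm38 chromosome 11, 32283511 to 32284465) stood at 63788 ± 14030 CPM (SD, n = 3), and the neutrophil alarmin genes S100a9 and S100a8 at 37811 ± 3442 and 27604 ± 6457 CPM. Actb, encoding cytoplasmic actin, reached 11434 ± 1018 CPM, the nuclear noncoding RNA Malat1 7506 ± 745 CPM and the neutrophil granule gene Ngp 7226 ± 1137 CPM. The 20 most abundant genes together held 41.1%, 45.6% and 46.1% of reads in replicates 1, 2 and 3. The β-globin genes Hbb-bs and Hbb-bt had 23569 ± 4824 and 11166 ± 2511 CPM. The entries Hbb-b1 and Hbb-b2 next to them held nearly equal reads, at 23487 ± 4822 and 11082 ± 2506 CPM, so the entries of a pair are not independent measurements. Both entries of each pair stayed in the library totals, the globin share and the 20 most abundant genes, so the same reads may count more than 1 time there. Among 31 gene lists fixed before the data were examined, 27 had a mean level under 1% of reads.

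After erythroid genes, neutrophil genes were the most abundant of the cell type lists, and their summed levels rose from primary to secondary and tertiary granule genes to genes of mature neutrophils, with the last step carried by S100a9 and S100a8. Primary granule genes, made in promyelocytes, held 0.261% ± 0.0426 of reads (SD, n = 3), with Mpo at 853 ± 149 CPM and the elastase gene Elane at 398 ± 96.7 CPM. Secondary and tertiary granule genes held 1.98% ± 0.272, with Ngp, Camp at 4726 ± 561 CPM and the lactoferrin gene Ltf at 1197 ± 238 CPM among them. Genes of mature neutrophils held 6.95% ± 1.03, of which S100a9 (chromosome 3, 90692632 to 90695721) made up 54.3%. The log2 ratio of the secondary and tertiary list to the primary list was 2.93 ± 0.06 (SD, n = 3), a 7.60-fold difference, and that of the mature list to the secondary and tertiary list was 1.81 ± 0.05, a 3.51-fold difference. Both ratios were above 0 in 3 of 3 libraries, and the two-sided exact sign-flip permutation p of 0.25 is the smallest that 3 libraries can give. S100a9 and S100a8 together made up 94.2% ± 0.470 of the mature list, and its other 13 members held 0.404% ± 0.0568 of reads. Without both genes, an alternative chosen after the data were seen, the second ratio turned to -2.29 ± 0.07. With the median log2(CPM + 1) of the members in place of the sum it turned to -2.49.

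The 3 neutrophil lists were lower in replicate 2 than in the other libraries. Primary granule genes held 0.297%, 0.214% and 0.272% of reads in replicates 1, 2 and 3 (exact binomial test against counting noise with Benjamini-Hochberg adjustment, adjusted p = 1.02e-239). Of the 12 members, 11 differed between libraries over all genes and 11 adjusted over the list alone, and 10 were lowest in replicate 2, or 9 with TMM scaling. Secondary and tertiary granule genes held 2.16%, 1.67% and 2.11%, with 14 of 14 members differing over all genes and 14 adjusted over the list alone. Mature neutrophil genes held 7.40%, 5.76% and 7.67%, with 14 of 15 members differing over all genes and 15 adjusted over the list alone. S100a8 ranged from 20324 CPM in replicate 2 to 32638 CPM in replicate 3, a 1.61-fold range. Glycolysis genes were also lowest in replicate 2, at 0.146%, 0.104% and 0.136% of reads, with 14 of 15 tested members lowest there and 12 differing over all genes, also 12 adjusted over the list alone. Immediate early genes were instead highest in replicate 2, at 0.347% of reads against 0.320% and 0.293%, with 10 of 14 tested members highest there, or 11 with TMM scaling. The glycolytic enzyme genes Aldoa, Pkm and Gpi1 had 255, 164 and 235 CPM, 255, 165 and 253 CPM, and 256, 178 and 247 CPM in replicates 1, 2 and 3. Replicate 2 lay furthest from the others for the neutrophil and glycolysis lists, so leaving it out narrows their spread by construction. Without it the coefficient of variation (CV) of the primary granule list went from 16.3% to 6.38% and of the secondary and tertiary list from 13.8% to 1.77%. That of the mature list went from 14.9% to 2.55% and of glycolysis from 17.1% to 5.08%. The primary granule list had a CV of 16.7% without replicate 1 and 23.0% without replicate 3. Also without replicate 2, Ngp, Pkm and Gpi1 no longer differed (adjusted p = 0.746, 0.841 and 0.325, exact binomial test), and S100a8 and Aldoa had CVs of 6.31% and 5.87% in place of 23.4% and 21.9%.

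Erythroid genes were lower in replicate 1 than in the other libraries. The list held 7.65%, 11.4% and 11.4% of reads in replicates 1, 2 and 3, with exact 95% Clopper-Pearson intervals that reached 0.225%, 0.192% and 0.181% of the value to either side. Of the 16 measured members, 15 differed over all genes and 15 adjusted over the list alone, and 12 were lowest in replicate 1, or 14 with TMM scaling. Hba-a1 had 47617, 71023 and 72724 CPM. The first enzyme of erythroid haem synthesis, Alas2, had 341, 463 and 477 CPM, and the erythroid transcription factor gene Klf1, named after its values were seen, had 47.0, 76.3 and 54.7 CPM. The haem synthesis and iron list was also lowest in replicate 1, at 0.267%, 0.305% and 0.308%, with 12 of 15 members differing over all genes and 12 adjusted over the list alone. Without replicate 1 neither list sum differed (adjusted p = 0.965 for erythroid and 0.182 for haem synthesis and iron, exact binomial test), but without their most abundant member both did (3.49e-66 and 0.00713). Also without replicate 1, Alas2 no longer differed (adjusted p = 0.310), while Hba-a1 still did (3.67e-37), with a CV of 1.67% in place of 22.0%. Without replicate 2 Klf1 no longer differed (adjusted p = 0.0569). The median gene of replicate 1 stood 0.13 log2 units above the other libraries on the scale of library totals and at -0.01 with TMM scaling, which gave erythroid levels of 7.16%, 11.6% and 11.9%.

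Haematopoietic stem and progenitor genes were a small part of these unsorted marrow libraries. On library totals, the members with at least 30 reads had a lower median CV than most random lists of single genes matched on expression. The 27 members together held 0.0767% ± 0.00726 of reads (SD, n = 3). The transcription factor genes Myb (chromosome 10, 21124935 to 21160984), Tal1 and Lmo2 were the highest, at 239 ± 38.5, 118 ± 11.9 and 109 ± 10.9 CPM. The surface sialomucin gene Cd34 (chromosome 1, 194938819 to 194961279) had 40.1, 40.6 and 41.5 CPM in replicates 1, 2 and 3 (exact binomial adjusted p = 1, CV 1.67%, both on library totals). The SD of its deposited log2 values, which carry the authors' scaling, was 0.101, against a median of 0.214 over genes with at least 30 reads. The stem cell factor receptor gene Kit had 17.2, 22.6 and 20.1 CPM (exact binomial adjusted p = 0.129, and 0.00872 with TMM scaling). Ly6a, which encodes Sca-1, had 6.46 ± 1.36 CPM, the signalling receptor gene Slamf1 3.77 ± 0.538 CPM and the transcription factor gene Hlf 6.32 ± 1.30 CPM. Of the members with fewer than 30 reads, Hoxb5 had 0 reads in all 3 libraries. That allows up to 0.114 CPM over all 26410388 reads, provided that reads of this gene could be counted. Procr had 3 reads in total, all in replicate 3, and Fgd5 had 0, 4 and 4 reads. Mecom had 4, 6 and 6 reads, and the 14 reads of Spink2 were all in replicate 1.

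Of the 22 stem and progenitor genes with at least 30 reads, 12 differed between libraries over all genes and 12 adjusted over the list alone, and their median CV of 13.8% lay at percentile 5.38 of 10000 random lists matched on expression. The ribosomal protein and skeletal muscle lists lay lower, at percentiles 5.18 and 1.48. The list held 0.0798%, 0.0818% and 0.0684% of reads in replicates 1, 2 and 3 (adjusted p = 1.35e-27, exact binomial test). With TMM scaling it held 0.0747%, 0.0834% and 0.0716%. On that scale 11 members were lowest in replicate 1 and 10 in replicate 3, and 13 were highest in replicate 2. Myb had 268, 254 and 195 CPM, the early progenitor factor Gata2 17.1, 12.2 and 7.44 CPM, and the cytokine receptor gene Flt3 12.5, 9.87 and 6.68 CPM. Without replicate 3 the list sum no longer differed on library totals (adjusted p = 0.181, exact binomial test), though without Myb, its most abundant member, it still did (0.00303). Also without replicate 3, Myb, Tal1 and Flt3 no longer differed (adjusted p = 0.134, 0.863 and 0.211, exact binomial test). Without replicate 1 Flt3 was not called (adjusted p = 0.0699), but its CV was 27.3% against 30.3%, a 1.48-fold difference, so most of its spread stayed. Without replicate 2 Lmo2 was not called (adjusted p = 0.567). Without replicate 3 the CV of Gata2 went from 39.5% to 23.7%, and Kit was called (adjusted p = 0.0409).

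**Figure D1:**
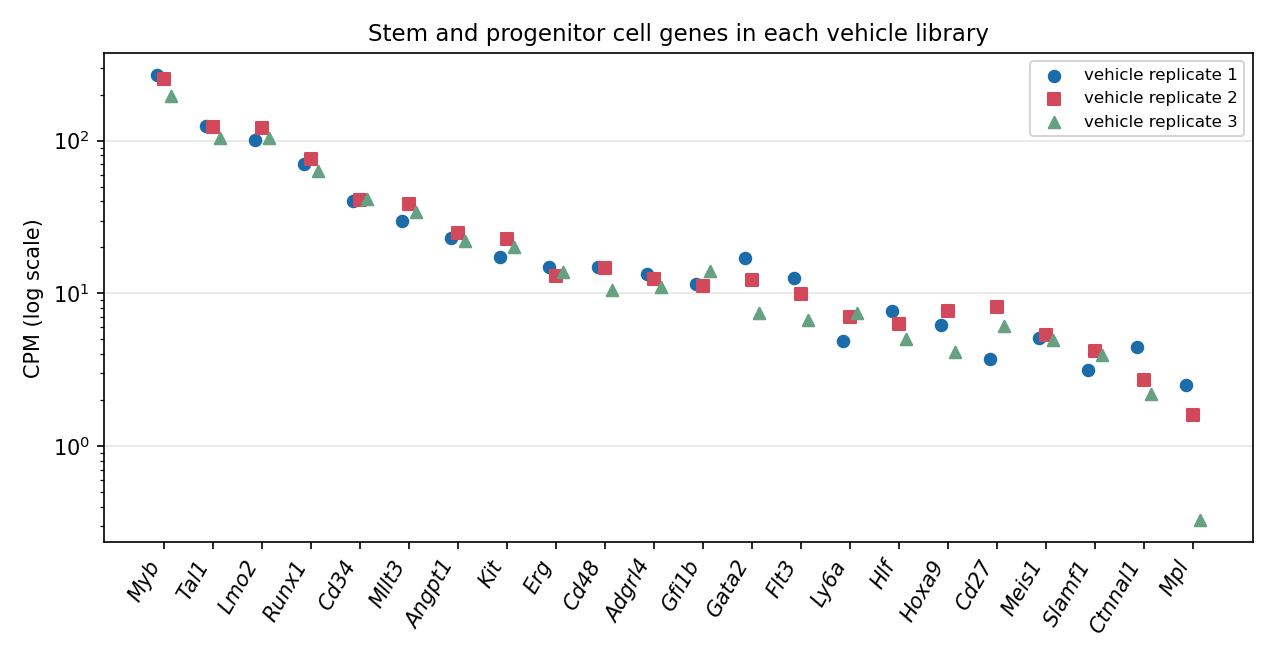
Level of each stem and progenitor gene with at least 30 reads in CPM on a log axis, with 1 symbol per vehicle replicate and genes ordered by mean level. Myb is highest at a mean of 239 CPM, and the 3 values of Cd34 lie between 40.1 and 41.5 CPM.

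As lists, early B cell, stromal and megakaryocyte genes were lowest in replicate 3. Early B cell genes held 0.105%, 0.0970% and 0.0751% of reads in replicates 1, 2 and 3, with 10 of 12 members differing over all genes and 11 adjusted over the list alone. Ebf1, a transcription factor required for B cell commitment, had 158, 160 and 104 CPM. Niche stroma and endothelium genes held 0.0431%, 0.0398% and 0.0298%, with 14 of 17 tested members differing over all genes and 15 adjusted over the list alone, and 13 lowest in replicate 3. The collagen gene Col1a2 had 94.2, 72.8 and 52.6 CPM, and Cxcl12, a chemokine that retains stem cells in the marrow, had 139, 134 and 110 CPM. Megakaryocyte and platelet genes held 0.108%, 0.0942% and 0.0869%, with 14 of 15 members differing over all genes and 14 adjusted over the list alone, among them the platelet factor gene Pf4 at 174, 162 and 136 CPM. Heat shock genes, a marker of cell stress, were lowest in replicate 3 as well, at 0.346%, 0.316% and 0.294% of reads, with 8 of 12 tested members lowest there, or 6 with TMM scaling. So were the plasma cell list and, with TMM scaling by a narrow margin to replicate 1, the stem and progenitor list. Without replicate 3 the CV went from 16.7% to 5.49% for the early B cell list and from 18.4% to 5.56% for stroma, and Ebf1, Cxcl12 and Pf4 no longer differed (adjusted p = 0.887, 0.528 and 0.128, exact binomial test), while the CV of Col1a2 went from 28.4% to 18.2%. Without replicate 1 the CV of the megakaryocyte list went from 11.2% to 5.70% and that of heat shock from 8.20% to 4.96%.

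Plasma cell genes held 0.0249%, 0.0239% and 0.0192% of reads in replicates 1, 2 and 3, with 4 of 8 tested members differing over all genes and 4 adjusted over the list alone. B cell genes held 0.0690%, 0.0670% and 0.0639%, and replicate 1 in place of replicate 3 was lowest with TMM scaling, at 0.0646%. Without replicate 3 neither list differed (adjusted p = 0.232 for plasma cell and 0.159 for B cell, exact binomial test), but the B cell list did without its most abundant member (0.0357). MHC class II genes held 0.0938% ± 0.00100 (SD, n = 3) and T and NK cell genes 0.0166% ± 0.000630. As whole lists they did not differ past counting noise on library totals (adjusted p = 0.560 and 0.151, exact binomial test), but with TMM scaling both did (adjusted p = 1.62e-14 and 5.99e-05). Of the 9 tested MHC class II members, 6 differed over all genes and 6 adjusted over the list alone. Without its most abundant member Cd74 the MHC class II list differed on library totals (adjusted p = 3.59e-06), though not without replicate 1 (0.397) or with TMM scaling (0.762). Skeletal muscle genes, a marker of tissue carried along from dissection, held 0.00161% ± 0.000175 and did not pass the test as a list (adjusted p = 0.239), with the calcium pump gene Atp2a1 at 5.89 ± 0.854 CPM.

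Monocyte and macrophage genes held 0.243% ± 0.00741 of reads (SD, n = 3), bone marrow macrophage genes 0.0555% ± 0.00346 and dendritic cell genes 0.0546% ± 0.00231. Myeloid transcription factor genes held 0.178% ± 0.00541, and among them Irf8, which directs monocyte and dendritic cell fate, had 321 ± 10.4 CPM. Each of these 4 list sums differed on library totals, but not when a particular library was left out: monocyte and macrophage without replicate 1 (adjusted p = 0.322), myeloid transcription factors without replicate 2 (adjusted p = 0.504), and bone marrow macrophage and dendritic cell without replicate 3 (adjusted p = 0.817 and 0.208, exact binomial test). Without its most abundant member the monocyte and macrophage list did differ without replicate 1 (3.47e-11), as did the myeloid transcription factor list without replicate 2 (0.000260). The dendritic cell list, of which Tcf4 made up 42.1%, also did not differ without that gene (adjusted p = 0.109), but did with TMM scaling (3.00e-07). Adipocyte genes held 0.0145%, 0.0186% and 0.0143% in replicates 1, 2 and 3, with 5 of 8 tested members differing over all genes and 5 adjusted over the list alone, and the list did not differ without replicate 2 (adjusted p = 0.748).

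**Figure D2:**
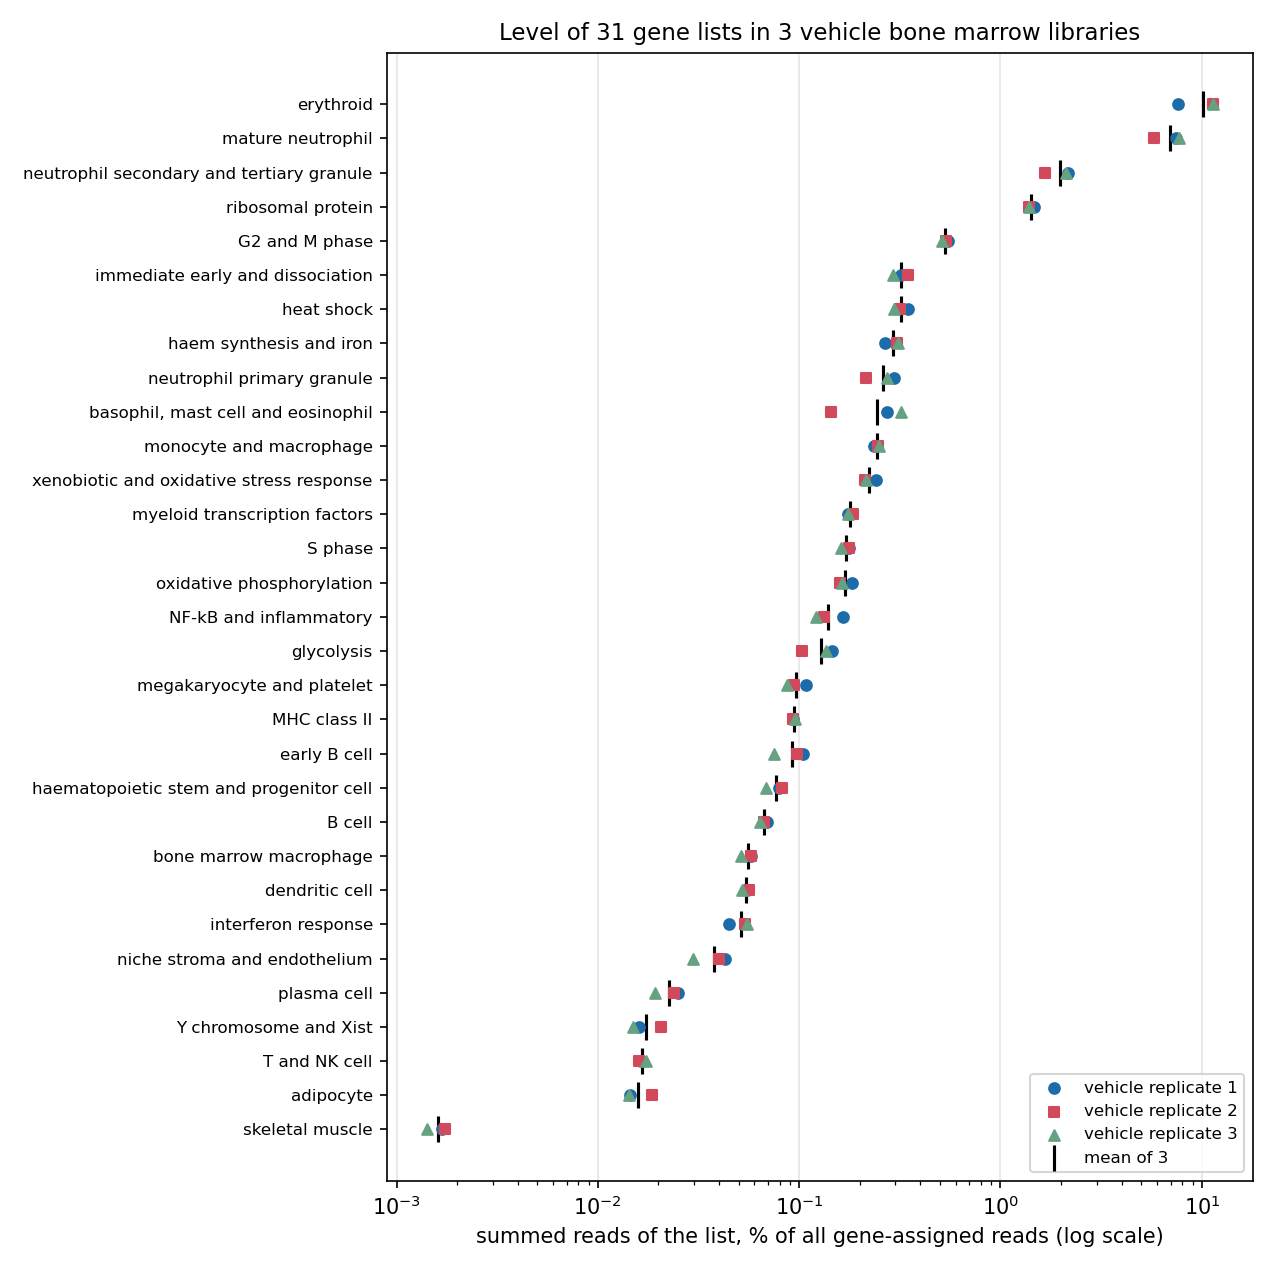
Summed reads of each of the 31 gene lists as a percent of all gene-assigned reads, on a log axis, with 1 symbol per vehicle replicate and a black tick at the mean of the 3. The erythroid list is highest at a mean of 10.1% and the skeletal muscle list lowest at 0.00161%.

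Ribosomal protein genes had the highest level of the housekeeping lists, at 1.42% ± 0.0489 of reads (SD, n = 3), with 23 of 24 members differing over all genes and 23 adjusted over the list alone. Cell cycle genes were well covered: the S phase list held 0.171% ± 0.00918 and the G2 and M phase list 0.533% ± 0.0212, including the proliferation marker Mki67 at 1183 ± 146 CPM and the topoisomerase gene Top2a at 960 ± 55.4 CPM. Oxidative phosphorylation genes held 0.168% ± 0.0120 and heat shock genes 0.319% ± 0.0261. Immediate early genes, which respond within minutes to cell handling, held 0.320% ± 0.0267 and were highest in replicate 2, at 0.320%, 0.347% and 0.293% in replicates 1, 2 and 3. The xenobiotic and oxidative stress list held 0.222% ± 0.0155. Interferon response genes held 0.0513% ± 0.00546, of which the antiviral gene Rsad2 made up 56.0%, and without Rsad2 the list did not differ between libraries on library totals (adjusted p = 1, exact binomial test), but did with TMM scaling (9.84e-05). On library totals without replicate 1, the ribosomal protein, interferon and xenobiotic lists no longer differed (adjusted p = 0.614, 0.170 and 0.682, exact binomial test). Nor did Rsad2 (0.257) and Top2a (0.691), and Top2a was also not called with TMM scaling. The CV of the oxidative phosphorylation list went from 7.11% to 1.95% without replicate 1 and that of heat shock from 8.20% to 4.96%. Without replicate 3 the S phase list no longer differed (adjusted p = 0.996) and the CV of the G2 and M phase list went from 3.99% to 1.47%. The ribosomal protein list, highest in replicate 1 on library totals, was lowest there with TMM scaling, at 1.38%, 1.41% and 1.46%. On that scale oxidative phosphorylation held 0.170%, 0.163% and 0.172%, the xenobiotic list 0.225%, 0.217% and 0.224%, and S phase 0.165%, 0.180% and 0.168%.

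NF-κB and inflammatory genes were as a sum highest in replicate 1, at 0.165%, 0.133% and 0.121% of reads in replicates 1, 2 and 3, with 9 of 10 tested members differing over all genes and 9 adjusted over the list alone. On library totals 5 members were highest in replicate 1 and 4 in replicate 2. With TMM scaling 3 were highest in replicate 1 and 6 in replicate 2. Heat shock genes were highest in replicate 1 as well on library totals, at 0.346%, 0.316% and 0.294%. With TMM scaling replicates 1 and 2 were nearly level for heat shock, at 0.324% and 0.322%. Of 4667 differing genes with at least 300 reads, 1693, 1452 and 1522 stood furthest apart in replicates 1, 2 and 3 on library totals. Of these, 1432, 486 and 323 were high and 261, 966 and 1199 low. The median gene of replicate 1 stood 0.13 log2 units above the other libraries on that scale and at -0.01 with TMM scaling. These counts were not made with TMM scaling. The interleukin gene Il1b, also a member of the mature neutrophil list, had 349, 155 and 205 CPM, a 2.24-fold range, and the neutrophil chemokine gene Cxcl2 had 395, 307 and 227 CPM. Without replicate 1 the CV of the list went from 16.0% to 6.57%, that of heat shock from 8.20% to 4.96% and that of Il1b from 42.4% to 19.5%, and without replicate 3 that of Cxcl2 went from 27.1% to 17.7%.

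Eosinophil granule genes were lower in replicate 2, and their list had the largest CV of the 31 summed list levels. This basophil, mast cell and eosinophil list held 0.272%, 0.143% and 0.319% of reads in replicates 1, 2 and 3, with exact 95% Clopper-Pearson intervals of 0.268% to 0.275%, 0.141% to 0.146% and 0.315% to 0.323%. Prg2 (chromosome 2, 84980461 to 84983632), which encodes the granule major basic protein, had 1219, 586 and 1560 CPM, and the eosinophil peroxidase gene Epx (chromosome 11, 87864000 to 87875536) had 174, 68.0 and 217 CPM. The eosinophil ribonuclease genes Ear1, Ear2 and Ear6 had 257, 142 and 365 CPM, 204, 107 and 272 CPM, and 193, 86.4 and 253 CPM, with reads between these paralogs not separable with certainty. The eosinophil receptor genes Ccr3, Siglecf and Il5ra, other members of the list named after the list's values were seen, had 15.7, 18.6 and 17.5 CPM, 9.49, 7.28 and 5.69 CPM, and 5.24, 8.39 and 7.33 CPM. The histidine decarboxylase gene Hdc was also lowest in replicate 2, at 427, 273 and 302 CPM. So were the basophil and mast cell protease genes Cpa3, Mcpt8 and Prss34, likewise named after the values were seen, at 30.2, 15.3 and 23.9 CPM, 63.3, 38.1 and 48.9 CPM, and 64.9, 43.2 and 61.6 CPM. The receptor genes Ms4a2 and Fcer1a of the same cells, named after the values were seen as well, were instead highest in replicate 2, at 6.44, 9.99 and 9.30 CPM and, from 33 reads in total, 0.982, 1.97 and 0.876 CPM. Of the 16 members, 13 differed over all genes and 13 adjusted over the list alone, and the median member CV of 35.9% lay at percentile 100 of 10000 matched random lists. The stroma and erythroid lists lay close to that, at percentiles 99.99 and 99.98. Neutrophil secondary and tertiary granule genes were lower in the same replicate 2, at 1.67% against 2.16% and 2.11%. Immediate early genes were highest there, at 0.347% against 0.320% and 0.293%. Without replicate 2 the CV of the list went from 37.2% to 11.3%, and those of Prg2, Epx, Ear1, Ear2 and Ear6 from 44.1% to 17.4%, 50.2% to 15.8%, 43.8% to 24.6%, 42.6% to 20.2% and 47.5% to 18.9%. Without replicate 2 Prss34 no longer differed (adjusted p = 0.533, exact binomial test) and the CV of Cpa3 went from 32.4% to 16.6%. Without replicate 1 that of Hdc went from 24.5% to 7.34%. Ms4a2 (adjusted p = 0.0435, exact binomial test) was not called without replicate 1 (0.820, CV 5.07% in place of 22.0%) or without replicate 2 (0.0808, CV 25.8%), and Fcer1a was not called (0.207). Siglecf (adjusted p = 0.0485, exact binomial test) was not called without replicate 1 (0.375), without replicate 3 (0.240) or with TMM scaling (0.222), and Il5ra (0.0860) was called without replicate 3 (0.0417) and with TMM scaling (0.0188).

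**Figure D3:**
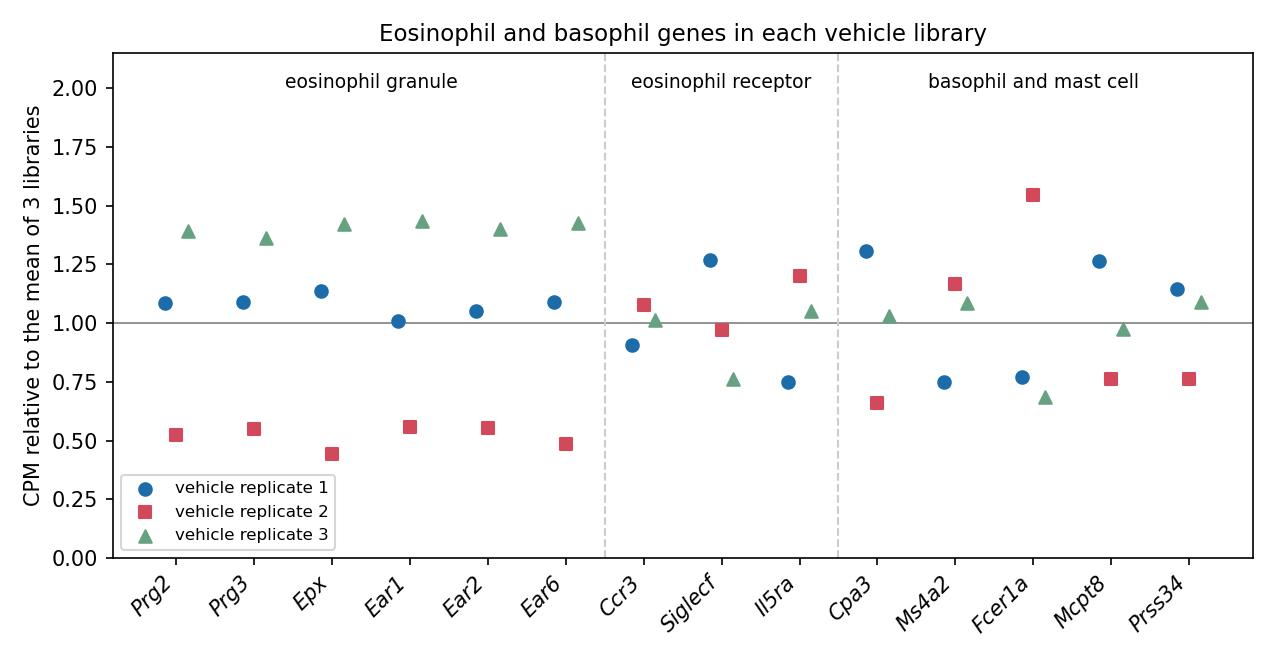
Level in CPM of eosinophil granule, eosinophil receptor, and basophil and mast cell genes in each vehicle replicate, divided by the gene's mean over the 3 libraries, with 1 symbol per replicate and a line at 1. The 6 granule genes are lowest in replicate 2, as for Prg2 at 586 CPM against 1219 and 1560 CPM, while the receptor gene Ccr3 lies between 15.7 and 18.6 CPM.

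Outside the eosinophil genes, the genes with the largest relative spread included Ifitm1, an interferon-induced membrane protein gene, at 46.7, 13.2 and 23.2 CPM in replicates 1, 2 and 3 (CV 62.1%). The collagen gene Col1a1 (chromosome 11, 94936224 to 94953042) had 36.8, 17.4 and 15.7 CPM, and Igfbp5 (chromosome 1, 72857932 to 72874884), encoding a secreted binder of insulin-like growth factors, had 275, 546 and 286 reads and was highest in replicate 2 at 67.4 CPM. The kinase gene Chuk had 18.1, 37.6 and 17.9 CPM, the ubiquitin ligase gene Arih2 69.7, 36.4 and 30.1 CPM and the focal adhesion gene Pxn 62.7, 49.6 and 111 CPM. Leaving out the library furthest from the others narrowed the spread of these genes, as it must. Without replicate 1 Col1a1 and Arih2 no longer differed (adjusted p = 0.562 and 0.0702, exact binomial test) and the CV of Ifitm1 was 38.8%. Without replicate 2 Igfbp5 and Chuk no longer differed (adjusted p = 0.761 and 1), and without replicate 3 the CV of Pxn went from 43.3% to 16.5%.

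Across all genes, 6584 of the 11833 with at least 30 reads (55.6%) differed between the 3 vehicle libraries by more than counting noise (exact binomial test of each library against the other 2, Benjamini-Hochberg adjustment). The median gene had a CV of 17.1%, against 8.23% from counting alone, and among the 1137 genes with at least 3000 reads these were 10.2% and 2.45%. The median SD of the deposited log2 values, which includes counting noise, was 0.21. Of the 31 lists, 28 differed beyond counting noise, and 27 did so without their most abundant member. Pearson correlations across genes, which are not independent replicates, were 0.973, 0.976 and 0.974 for replicates 1 and 2, 1 and 3, and 2 and 3, with Spearman values of 0.973, 0.976 and 0.973. The chi-square per degree of freedom was 20.7, 18.8 and 13.1, so no pair agreed within sampling noise. Each library was counted separately, but technical spread can exceed sampling noise too, so these values do not show that the libraries are independent replicates. Leaving out replicate 1, 2 or 3 gave 3781, 4318 and 4250 genes.

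Y-linked genes were detected in each library, which the labels give as male. Ddx3y (chromosome Y, 1260771 to 1286629) had 94.9, 131 and 96.0 CPM, Uty 23.3, 31.3 and 20.7 CPM, Eif2s3y 22.7, 20.1 and 17.6 CPM and Kdm5d 17.3, 19.6 and 11.6 CPM. Xist, the RNA that silences an X chromosome in female cells, had 3.77 ± 0.905 CPM (SD, n = 3), a total of 25, 35 and 39 reads. The 5 genes together held 0.0173% ± 0.00301 of reads, and without replicate 2 the list and Ddx3y and Uty did not differ (adjusted p = 0.0786, 0.904 and 0.374, exact binomial test), nor did Kdm5d without replicate 3 (0.439). Without replicate 2 Eif2s3y differed (0.0476), as did the list without its most abundant member (0.00142).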

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

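The authors' scaling, the share without Rn45s and globin entries, the mature neutrophil list without S100a8 and S100a9, lists without their most abundant member under TMM scaling or with 1 library left out, and correlations at 300 reads or more were chosen after the data were seen. The number of genes past counting noise stayed within 1.5 times of 6584 with TMM scaling (6014, of which 5298 were shared), median-of-ratios (6016), without the 20 most abundant genes (6065), with the authors' scaling (6038), with at least 1 read (7102) or 300 reads (4758), and with a chi-square test (6967). Leaving out 1 library gave 3781 to 4318 genes, from a test of 1 pair with fewer reads. The median SD of log2 values was 0.214 and became 0.228 on library totals, 0.220 with at least 1 read, 0.169 with at least 300, 0.232 with a pseudocount of 0.1, and 0.167 to 0.177 with 1 library left out. The DESeq2 gene-wise dispersion was not run on the recovered reads, by the same choice to keep to the deposited log2 unit. No paired analysis was possible because the libraries form 1 group.

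Removing abundant genes changes the denominator and drops list members among them. Without the 20 most abundant genes the lists held 0.467% (primary granule), 1.41% (secondary and tertiary granule), 0.308% (mature neutrophil), 0.518% (erythroid), 0.439% (basophil, mast cell and eosinophil) and 0.138% (stem and progenitor). Without Rn45s and globin entries they held 0.386%, 2.93%, 10.3%, 0.359%, 0.361% and 0.114%. The other 25 lists moved by factors of 0.822 to 1.80 and 1.48 to 1.49 under these settings, and by 0.946 to 0.956 with the authors' scaling. The library with the lowest level was the same under library totals, TMM and the authors' scaling for 19 of 31 lists. The log2 ratio of mature to secondary and tertiary neutrophil genes reversed to -2.49 with the median of members and to -2.29 without S100a8 and S100a9, while the sum without the most abundant member, which keeps S100a8, gave 1.32. MHC class II and T and NK cell lists crossed the threshold with each of 3 other scalings. Of 92 genes followed, leaving out replicate 1, 2 or 3 ended the call of 13, 18 and 16 and added 0, 1 and 2, and TMM scaling ended 3 and added 4. Depth limits the stem cell genes with under 30 reads, which were not tested.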

Other observations

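The tests of scaling and of shared reads for the eosinophil genes, and of scaling for the globins, were chosen only after the result was seen. Stromal and adipocyte genes had the highest median member CVs of the 31 lists, 37.4% and 36.8%. The fatty acid binding protein gene Fabp4 had 13.5, 22.7 and 5.03 CPM in replicates 1, 2 and 3, the complement factor gene Cfd 1.09, 4.94 and 0.766 CPM from 10, 40 and 7 reads, and the leptin receptor gene Lepr, a marker of niche stroma, 7.31, 10.5 and 1.97 CPM. Among immediate early genes, Fosb had 129, 190 and 122 CPM and Atf3 34.9, 70.7 and 52.2 CPM. The recombination gene Rag1 had 68.5, 55.6 and 43.9 CPM and the terminal transferase gene Dntt 70.1, 45.4 and 43.3 CPM, with Dntt not differing without replicate 1 (adjusted p = 0.692, exact binomial test). Without replicate 3 Lepr did not differ (adjusted p = 0.0780) and the CV of Fabp4 went from 64.2% to 35.8%, while the CV of Rag1 went from 22.0% to 14.6%. Without replicate 2 Fosb did not differ (adjusted p = 0.248) and the CV of Cfd went from 102% to 24.7%, and without replicate 1 the CV of Atf3 went from 34.0% to 21.3%.

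The 6 eosinophil granule genes were lower in replicate 2, with a median log2 ratio to the other libraries of -1.20 (SD over genes 0.16). Fewer eosinophils would lower their other transcripts too, but the receptor genes Ccr3, Siglecf and Il5ra had a median of 0.17 (SD over genes 0.24). That argues against a loss of these transcripts in proportion to the granule genes, and does not cover other eosinophil transcripts. The receptor genes had only 455, 198 and 183 reads over all libraries, and the SD over genes does not cover counting error. A scaling shared by granulocyte genes is argued against by the distance of -0.85 to the neutrophil secondary and tertiary granule genes, and reads shared between Ear paralogs by -1.38 for Prg2 and Epx, which are no Ear genes. The 5 basophil and mast cell genes had a median of -0.55 (SD 0.80), so some of them were lower as well, and a different mix of eosinophil stages is a candidate explanation left open. Of biological explanations only fewer eosinophils was tested.

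Globin reads were lower in replicate 1, with a median log2 ratio of -0.59 (SD over genes 0.03) for Hba-a1, Hbb-bs and Hbb-bt, and -0.46 (SD 0.16) for 5 late erythroid genes. A library-wide scaling is argued against, since the globins lay at -0.73 relative to the median of all tested genes. Red cells left after lysis may have differed, which would leave nucleated precursors unchanged. On library totals 6 precursor genes had a median of -0.22 (SD 0.18), between the values set for either outcome. The median of all tested genes was 0.13 on that scale, and the 6 precursor genes all lay lower, from -0.48 to -0.02. The values set had not allowed for that shift, so this test cannot tell carry-over and fewer erythroid cells apart. No other biological explanation was tested.

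Among neighbouring entries with at least 300 reads, 17 pairs held reads within 2% of each other in every library, such as Wdr89 and Rplp2-ps1 with 13614, 10095 and 11351 reads against 13603, 10095 and 11345. Chance is argued against, since 0 pairs were found among entries 5 apart. Reads counted in both of 2 overlapping genes are consistent with the 69.2% of the 13 pairs with RefSeq coordinates (9 pairs) that overlap. The other 4 pairs, Hbb-bs with Hbb-b1, Hbb-bt with Hbb-b2, and the genes Atp6v0c and Akr1b3 each with a pseudogene (Atp6v0c-ps2 and Gm6644), do not overlap by those RefSeq coordinates, so another cause is open for them. A single RefSeq position per symbol was compared. The GENCODE annotation held Hbb-bs and Hbb-bt but no gene named Hbb-b1 or Hbb-b2, so the globin pairs may not be separate genes of that annotation. No biological explanation was tested.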
